A study of Mus musculus with 33 samples.

How the data were processed

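The data are bulk RNA sequencing of mouse nucleus accumbens, a ventral striatal region, in 33 libraries that the labels place in 6 groups. Each library is taken as 1 mouse, as its title gives it. Conventionally raised mice drank water (H2O, a normal microbiome) or a mixture of non-absorbable antibiotics and an antifungal (Abx, a depleted microbiome) with 0.5 mg/mL vancomycin, 0.5 mg/mL bacitracin, 2 mg/mL neomycin and 1.2 µg/mL pimaricin, from 2 weeks before the injections and throughout. They were 7 to 9 weeks old, came from a commercial supplier and, per the labels, were those of an earlier publication. Whole cages were assigned to a drink. Germ-free mice (GF), matched in age, were bred and kept in isolators in a germ-free facility of the institution. All mice were C57BL/6J. Mice were given saline or 20 mg/kg of morphine per day for 7 days. Polyadenylated RNA was made into cDNA with a SMARTer kit and sheared before library preparation. The labels give neither the cage of a mouse nor a batch or sequencing date, so whether GF and conventional mice were sequenced together is unknown. Genome build, gene annotation and strand setting are not given in the sources used here.

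The deposited count table holds read counts per gene symbol that the authors made, and its values are whole numbers. Per the submitters' processing notes, FastQC, STAR 2.4.0 and edgeR were used. The names of its 5 tally entries are those the program HTSeq writes, although the counting program is not stated. A second deposited table holds a normalised signal that the authors computed. In each library, that signal equals the count divided by 1 constant, for the 10855 genes compared between both tables, and it covers 10871 genes against 24053 in the count table. Counts were used for every test here. Spreadsheet software had turned 27 gene names into dates. Of these, 19 were restored by matching their values to the normalised table, and 8 were left out.

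Reads counted to genes ranged from 4.87 to 15.3 M (megareads) per library, and 19.3% to 35.4% of the tallied reads were given to no gene. The log2 CPM of pairs of libraries of 1 group correlated across genes with r from 0.960 to 0.993, and no pair was close enough to be a repeat of 1 library (chi-squared per degree of freedom 3.12 to 37.3). The numbers in the titles were tested as a possible pairing of mice across groups and did not pair them: 66 pairs with the same number had a mean r of -0.000700, from -0.473 to 0.462.

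Differences were tested in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr at its minimum count of 10, which left 14602 genes. Libraries were scaled by TMM factors, and a single fit with 6 group means covered all 33 libraries, with 27 residual degrees of freedom and a common biological coefficient of variation of 0.128. Quasi-likelihood tests (glmQLFit, glmQLFTest) were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes, which also stand in parentheses after gene names, are given ± their standard error where one is printed, and levels as CPM, counts scaled to a common library size, as mean ± SD over the libraries of a group. The 8 pairwise comparisons were the microbiome states within saline mice, morphine against saline within each state, and GF or Abx against H2O within morphine mice. Differences between morphine responses were tested as 2 interactions.

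Gene lists were tested with camera on the same fit, two-sided, at a preset inter-gene correlation of 0.01. Of 41 lists, 39 had the 3 tested members that were required. The median of a list is that of its members' log2 fold changes. Adjusted p with a correlation estimated from the data are given beside those of the preset one. The comparisons, the tests, the lists and the rule for named genes were fixed before the data were examined. That rule took, in pairwise comparisons with enough calls, the 12 higher and the 12 lower genes with the largest change among those past the threshold with a mean of at least 2 CPM in a compared group. It left out gene models, pseudogenes, ribosomal protein genes and mitochondrial genes. In interactions it took 6 and 6, and where fewer than 10 genes passed it took those and the 5 with the smallest p. List members past the threshold or with the smallest p were added, as were Drd1a, Drd2, Oprm1, Penk, Pdyn, Fkbp5, Sgk1 and Fos in all comparisons. No positions are given, since the tables hold symbols alone.

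The analysis code was tested on simulated data. With changes of 1.5-fold planted in group sizes and depths like these, 52.2% to 73.1% were recovered in the pairwise comparisons and 40.3% and 47.8% in the interactions. At 2-fold the lowest shares were 83.3% and 71.2%. Alternatives set beforehand were DESeq2 1.42.0, limma voom with sample quality weights, RLE and upper-quartile factors, no filter, a CPM filter, a fit of only the groups compared, a block for the replicate number, a surrogate variable from sva 3.50.0, the levels of glutamatergic neuron and myelin genes as covariates (dissection covariates), a threshold of 0.10 and leaving out each library. Alternatives added after seeing the data were the genes of the normalised table alone, a correction of GC content and gene length by splines with 5 degrees of freedom per library, thinning of all libraries to 4874293 reads, and leaving out GF saline replicate 1 and GF morphine replicate 5. Length and GC content came from a reference annotation for 98.4% of genes by symbol. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.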

Results

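RNA from the nucleus accumbens was sequenced from 6 H2O saline, 6 Abx saline, 6 GF saline, 5 H2O morphine, 5 Abx morphine and 5 GF morphine mice. Reads counted to genes (M, megareads) averaged 11.2 ± 0.966 M in H2O saline, 10.4 ± 1.23 in Abx saline, 12.7 ± 2.15 in H2O morphine and 12.6 ± 0.943 in Abx morphine libraries (SD). They averaged 8.32 ± 3.62 M in GF saline and 6.63 ± 0.580 in GF morphine libraries. GF saline replicate 1 held 15.3 M reads, while the other 10 GF libraries held 4.87 to 8.13 M and the 22 libraries of conventional mice 9.36 to 15.3 M. Slc17a7, a vesicular glutamate transporter gene of cortical-type neurons, varied from 2.41 to 1248 CPM and averaged 64.8 ± 120 CPM in GF saline and 281 ± 205 in H2O saline libraries. The pituitary hormone gene Gh averaged 15.2 ± 20.3 CPM in GF saline, 11.9 ± 13.4 in GF morphine and 0.516 ± 0.892 in H2O saline libraries, and had no read in GF saline replicate 1. On the first principal component that library stood at -15.5, the other GF libraries at 11.9 to 34.2 and those of conventional mice at -29.3 to 12.6. For Hspa5 and Tsc22d3 it lay with the GF libraries, and both genes were called higher in GF saline mice with this library included. Hspa5 stood at 583 CPM (conventional libraries 256 to 419, other GF libraries 499 to 763). Tsc22d3 stood at 115 CPM (50.8 to 94.2 and 82.4 to 199). Its identity cannot be checked from the labels.

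**Figure D1:**
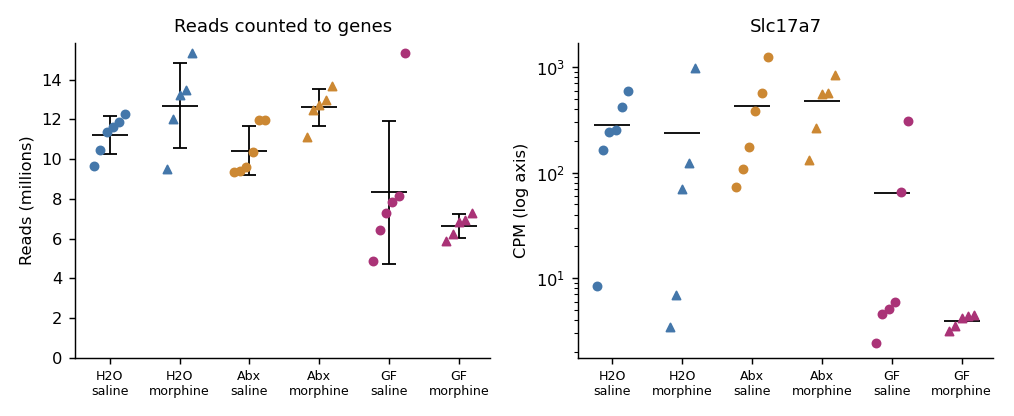
Left, reads counted to genes in M per library in each of the 6 groups; right, Slc17a7 in CPM on a log axis. Points are libraries; the bar is the mean, with the SD in the left plot, where 10 of the 11 GF libraries lie between 4.87 and 8.13 M.

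**Figure D2:**
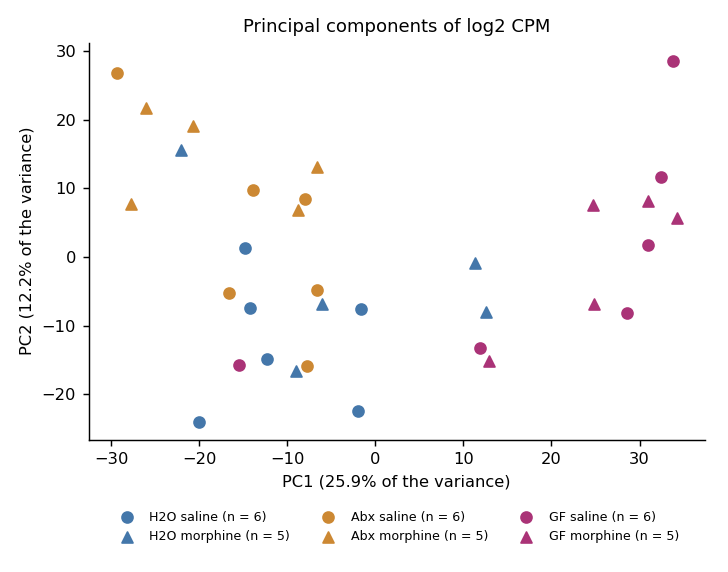
Libraries by the first and second principal components of log2 CPM, which hold 25.9% and 12.2% of the variance; colour gives the microbiome state and shape the injection.

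GF saline mice were compared with H2O saline mice, which asks how germ-free status goes with expression in this region and also compares mice of separate breeding facilities. Glucocorticoid-response genes were higher in GF mice. Of 23 tested members 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.35, a camera adjusted p = 1.58e-08, and adjusted p = 0.0946 with an estimated correlation. The level of the list was above every H2O saline library in 6 of 6 GF libraries. Plin4, which codes for a lipid-droplet coat protein, rose from 2.97 ± 1.20 to 21.7 ± 11.2 CPM (2.81 ± 0.40, adjusted p = 1.12e-05, higher in 6 of 6 libraries). Zbtb16, a transcription factor gene, rose by 2.42 ± 0.29, the kinase gene Sgk1 by 1.27 ± 0.17, Tsc22d3, the gene of a glucocorticoid-induced leucine zipper protein, by 1.34 ± 0.14, Pdk4 by 1.05 ± 0.12, Hif3a by 1.61 ± 0.25 and Fkbp5, a co-chaperone gene of the glucocorticoid receptor, by 0.31 ± 0.11 (adjusted p = 0.0334, above every H2O library in 5 of 6). Chaperone genes of the heat-shock list were higher as well: 14 of 16 rose and 0 fell (14 and 0 adjusted over the list alone), with median 0.49, adjusted p = 7.91e-11 and adjusted p = 0.0946 with an estimated correlation. Hspa5, the main chaperone gene of the endoplasmic reticulum, rose by 0.95 ± 0.10 (adjusted p = 1.2e-07, 6 of 6 libraries above the H2O range), Hspa1b by 1.97 ± 0.43, Hspa8 by 0.45 ± 0.06 and Hsp90aa1 by 0.38 ± 0.08.

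Genes of oxidative phosphorylation were lower in GF saline than in H2O saline mice: 36 of 59 fell and 0 rose (38 lower adjusted over the list alone), with median -0.18, adjusted p = 1.8e-10 and adjusted p = 0.787 with an estimated correlation. The median was -0.12 after a correction of GC content and length. Examples are Uqcr11 (-0.36), Ndufs8 (-0.32), Atp5k (-0.29) and Sdhb (-0.24). Among 23 genes of cholesterol synthesis and uptake 10 fell and 1 rose (11 and 1 adjusted over the list alone), with median -0.21, adjusted p = 0.00467 and adjusted p = 0.845 with an estimated correlation; Insig1 (-0.45) and Dhcr7 (-0.42) fell, and Idi1 (0.40) rose. Vessel markers were lower. In the endothelial list 9 of 20 fell and 3 rose (9 and 3 adjusted over the list alone), with median -0.23, adjusted p = 0.0207 and adjusted p = 0.845 with an estimated correlation: the tight-junction gene Cldn5 (-0.85) and the growth-factor receptor gene Kdr (-0.80) fell, while the glucose transporter gene Slc2a1 (0.38) rose. In the mural list 4 of 12 fell and 0 rose (4 and 0 adjusted over the list alone), among them Pdgfrb (-0.72) and Vtn (-0.77), with median -0.22, adjusted p = 0.00248 and adjusted p = 0.562 with an estimated correlation.

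Genes of signalling by the inhibitory transmitter GABA passed as higher at the preset correlation in GF saline mice: 9 of 21 rose and 1 fell (10 and 1 adjusted over the list alone), with median 0.24, adjusted p = 0.0461 and adjusted p = 0.787 with an estimated correlation. Gabrb2 (0.74) and Gabra2 (0.57), which also differs between C57BL/6 substrains, rose and Gabrd (-0.55) fell. Of 5 genes of the aryl hydrocarbon response 3 rose and 0 fell (4 and 0 adjusted over the list alone), Tiparp (1.10) and Cyp1b1 (0.97) among them, with median 0.30, adjusted p = 0.0207 and adjusted p = 0.0951 with an estimated correlation. In the list of medium spiny neurons, the principal cells of this region, 5 of 20 fell (1 adjusted over the list alone), with median -0.34, adjusted p = 0.00548 and adjusted p = 0.927 with an estimated correlation; Ppp1r1b fell by 0.46 (adjusted p = 0.0371, 4 of 6 libraries below the H2O range). The mu opioid receptor gene Oprm1 rose by 1.11 ± 0.26 (adjusted p = 0.00164, 6 of 6 libraries above the H2O range) and the nociceptin receptor gene Oprl1 by 0.33 (adjusted p = 0.0449, 4 of 6). The dopamine receptor genes Drd1a (-0.15, adjusted p = 0.599) and Drd2 (-0.29, 0.334), the opioid peptide genes Penk (-0.23, 0.252) and Pdyn (-0.34, 0.161), and Fos (0.70, 0.149) did not pass, here or in any of the 10 comparisons. Without GF saline replicate 5 the Drd1a value was 0.01.

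The genes that rose most in GF saline mice included Gh and Prl, both pituitary hormone genes, with 2.35 ± 3.75 CPM of Prl in GF saline and 0.0645 ± 0.158 in H2O saline libraries. Gal (2.68), Avpr1a (2.23), Prlr (2.20), Irs4 (2.13), Zim1 (2.03), Tekt4 (2.02) and Crh (1.59) also rose. Gal was above the H2O range in 2 of 6 libraries and the others in 5 of 6. The list of neighbouring hypothalamic tissue stood at 1.70 ± 1.28 in GF saline and 0.61 ± 0.38 in H2O saline libraries (mean log2 CPM ± SD). The largest falls were those of Tnnt1 (-2.64), Fam181a (-1.86), Alas2 (-1.67), Trib3 (-1.58), Tnfsf10 (-1.37), Cd248 (-1.25), Gja5 (-1.22), Slc35f2 (-1.21), Clec14a (-1.18), Stra6 (-1.15), Rcor2 (-1.12) and Arl5c (-1.10). In all, 4807 of 14602 genes (32.9%) passed the edgeR test, 2622 higher and 2185 lower, with a median absolute log2 fold change of 0.35, and 204 of them changed over 2-fold. With upper-quartile factors 2122 were higher and 2856 lower. Of 39 lists 11 passed camera, and 0 with an estimated correlation. GF libraries had lower depth, and log2 fold changes correlated across genes with gene length (Spearman rho 0.335) and GC content (rho -0.494), genes not being independent replicates. After a correction of GC content and length the count was 2521, with 1309 higher and 1212 lower.

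Abx saline mice were compared with H2O saline mice, which asks what depletion of the microbiome in adults goes with. Glucocorticoid-response genes were higher. Over all genes 2 of 23 rose and 0 fell, and 10 rose adjusted over the list alone, with median 0.32, adjusted p = 1.17e-10 and adjusted p = 0.0392 with an estimated correlation; the level of the list was above every H2O library in 6 of 6 Abx libraries. Plin4 rose from 2.97 ± 1.20 to 17.2 ± 13.5 CPM (2.52 ± 0.40, adjusted p = 0.00217, 6 of 6 libraries) and Hif3a by 1.27 ± 0.25, while Sgk1 (0.65, adjusted p = 0.12) and Fkbp5 (0.33, 0.229) did not pass over all genes. Microglia genes were lower: 2 of 20 fell over all genes and 14 adjusted over the list alone, with median -0.25, adjusted p = 1.08e-20 and adjusted p = 0.0392 with an estimated correlation. Olfml3 fell by 0.80 (adjusted p = 0.000807, below every H2O library in 6 of 6) and Fcrls fell by 0.55. In the myelin list Gjb1 (-0.71) fell over all genes and 9 members adjusted over the list alone, with median -0.32, adjusted p = 1.94e-13 and adjusted p = 0.308 with an estimated correlation. Other cell-type lists passed camera as lower at the preset correlation alone. These were medium spiny neurons (median -0.18), endothelium (-0.15), mural cells (-0.14) and oligodendrocyte precursors (-0.12).

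The RNA-binding protein gene Rbm3 rose from 56.0 ± 3.47 to 87.2 ± 13.9 CPM in Abx saline mice (0.64 ± 0.08, adjusted p = 0.000102, 6 of 6 libraries). Rasd1 (1.11), a gene known to be induced by dexamethasone, and Usp51 (1.21), Zfp568 (0.93), Hspa2 (0.36) and Crkl (0.26) rose too. Klk6 (-1.04), Hist1h2bc (-0.62), Tmem98 (-0.56) and the lysosomal enzyme genes Hexa (-0.27) and Tpp1 (-0.22) fell. Septal and ependymal markers of neighbouring tissue differed between the same groups. The septal list had 0 members past the threshold and 4 higher adjusted over the list alone, with median 0.78, adjusted p = 6.8e-05 and adjusted p = 0.198 with an estimated correlation, Zic1 at 0.78 and Zic2 at 0.79. The ependymal list had 0, and 4 higher and 1 lower adjusted over the list alone, with median 0.83, adjusted p = 0.00443 and adjusted p = 0.6 with an estimated correlation. Over all genes 17 passed the edgeR test, 9 higher and 8 lower, 1752 had an unadjusted p under 0.05, and 13 of 39 lists passed camera, 2 with an estimated correlation. The count of 17 was 4 without H2O replicate 5 or Abx replicate 4, 5 without H2O replicate 8 or 9, 7 without Abx replicate 5, 8 without H2O replicate 6 or Abx replicate 6, 11 without Abx replicate 2, 30 without Abx replicate 1 and 31 without Abx replicate 3. It was 100 by DESeq2 and 187 by limma voom.

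GF saline mice were also compared with Abx saline mice, 2 states without a normal microbiome. Chaperone genes were higher in GF mice: 14 of 16 rose and 0 fell (15 and 0 adjusted over the list alone), with median 0.46, adjusted p = 8.07e-17 and adjusted p = 0.0294 with an estimated correlation, and the level of the list was above every Abx library in 6 of 6 GF libraries. Hspa5 rose by 0.99 ± 0.10 (adjusted p = 3.92e-08, 6 of 6 libraries), Chordc1 by 1.09, Hspa4l by 0.84 and Hspa1b by 1.65. Among glucocorticoid-response genes 5 of 23 rose (4 adjusted over the list alone), with median 0.16, adjusted p = 0.0192 and adjusted p = 0.901 with an estimated correlation, Zbtb16 (1.32), Tsc22d3 (1.03), Pdk4 (0.83) and Sgk1 (0.62, adjusted p = 0.00714, 6 of 6 libraries) among them. The myelin and microglia lists passed as higher at the preset correlation alone, and those of astrocytes and oligodendrocyte precursors did not pass. In the myelin list 7 of 20 rose (10 adjusted over the list alone), with median 0.34, adjusted p = 0.00117 and adjusted p = 0.901 with an estimated correlation. Its level was above every Abx library in 3 of 6 GF libraries and below every one in 1 of 6. In the microglia list 7 of 20 rose (9 adjusted over the list alone), such as Gpr34 (1.31), with median 0.19, adjusted p = 0.0044 and adjusted p = 0.901 with an estimated correlation.

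GABA signalling genes passed as higher in GF than in Abx saline mice, with 7 of 21 up (8 adjusted over the list alone), median 0.20, adjusted p = 0.00374 and adjusted p = 0.507 with an estimated correlation, Gabra2 (0.79) among them. Of 59 oxidative phosphorylation genes 20 fell (20 adjusted over the list alone), with median -0.11, adjusted p = 1.56e-05 and adjusted p = 0.901 with an estimated correlation. Their median was -0.06 after the correction of GC content and length. Oprm1 rose by 0.89 ± 0.25 (adjusted p = 0.00951, 3 of 6 libraries). The largest rises were those of Gh and of Prl, which had no read in Abx saline libraries, and of Oxt (4.53, with 3 of 6 GF libraries above the Abx range), Gal (2.82; -0.42 with dissection covariates), Cml5 (1.84), Prlr (1.66), Apoo (1.65), Mab21l1 (1.64), Avpr1a (1.64), Chrna2 (1.63) and Fam19a4 (1.47). Neurod2 (-2.60) and Fezf2 (-1.54), markers of cortical glutamatergic neurons, were among the largest falls, with Prdm12 (-2.39), Nov (-2.26), Tnnt1 (-2.10), Bmp3 (-1.96), Fam181a (-1.90), Vip (-1.79), Tmem40 (-1.78), Gucy2g (-1.76), Nmbr (-1.73) and Ptpn3 (-1.60). Slc17a7 averaged 64.8 ± 120 CPM in GF saline and 427 ± 445 CPM in Abx saline libraries. Of all genes 3990 passed the edgeR test, 2103 higher and 1887 lower, and with upper-quartile factors 1723 were higher and 2473 lower. Of 39 lists 8 passed camera, 1 with an estimated correlation. Log2 fold changes of this comparison correlated across genes with gene length (rho 0.263) and GC content (rho -0.501), which bears on lists that rose as well as those that fell. Correcting GC content and length left 2164 genes past the threshold, and 2278 passed in a fit of both groups alone.

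**Figure D3:**
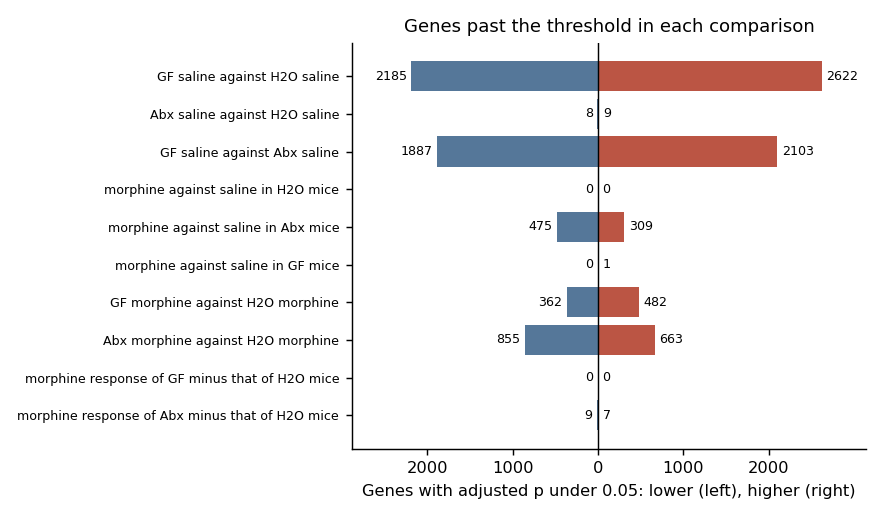
Genes past an adjusted p of 0.05 in the 10 comparisons, lower to the left and higher to the right, with their numbers. The counts run from 0 for morphine in H2O mice to 4807 for GF against H2O saline mice. All come from the single fit, which pools the variance of groups with unequal spread.

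Morphine was compared with saline in H2O mice to give the response under a normal microbiome. No gene passed the edgeR test (0 of 14602, smallest adjusted p = 0.066), while 2223 had an unadjusted p under 0.05. DESeq2 called 332 genes, limma voom 1314 and a fit of both groups alone 989. The single fit pools the variance of all 6 groups, whose spread was unequal. Chi-squared per degree of freedom between libraries reached 37.3 in GF saline and 11.2 in H2O saline mice. A count of 0 from this fit does not show that no gene responded. Among the genes with the smallest p were Fndc3a (0.36), Slc9a7 (0.75), Erbb4 (0.81) and Klhl11 (0.62), each at an adjusted p of 0.066 and above every saline library in 5 of 5 morphine libraries. Oprm1 had a log2 fold change of 1.05 ± 0.26 (adjusted p = 0.0794, 4 of 5 libraries). Among the lists, ribosomal protein genes were lower (19 of 77 adjusted over the list alone, 0 over all genes), with median -0.13, adjusted p = 8.36e-20 and adjusted p = 0.59 with an estimated correlation, as were oxidative phosphorylation genes (24 of 59, 0 over all genes), with median -0.14, adjusted p = 1.33e-18 and adjusted p = 0.526 with an estimated correlation. Log2 fold changes of this comparison correlated across genes with gene length (rho 0.426) and GC content (rho -0.299). After their correction these medians were -0.07 and -0.09. The microglia list had 1 lower member adjusted over the list alone, C1qc (-0.37, adjusted p over all genes = 0.0673, 5 of 5 libraries below the saline range), with median -0.20, adjusted p = 7.3e-08 and adjusted p = 0.526 with an estimated correlation. The endothelial list had 4 lower adjusted over the list alone, with median -0.16, adjusted p = 5.06e-05 and adjusted p = 0.526 with an estimated correlation. The lists of medium spiny neurons (median -0.19) and myelin (-0.18) also passed as lower, and that of GABA signalling (0.12) passed as higher. In all 8 lists passed camera, and 0 with an estimated correlation. The glutamatergic neuron list passed as lower although its median was 0.01 and its mean -0.01 (adjusted p = 0.698 with an estimated correlation), and the median was below 0 with DESeq2. The number of genes called was 1 without saline replicate 6 and 2 without morphine replicate 4.

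Morphine was compared with saline in Abx mice to give the response under a depleted microbiome. Glucocorticoid-response genes rose: 10 of 23 were higher and 0 lower (12 and 1 adjusted over the list alone), with median 0.33, adjusted p = 1.66e-09 and adjusted p = 0.0718 with an estimated correlation, the level of the list being above every saline library in 5 of 5 morphine libraries. Plin4 rose from 17.2 ± 13.5 to 56.1 ± 7.44 CPM (1.70 ± 0.33, adjusted p = 0.00285, 5 of 5 libraries), the cell-cycle inhibitor gene Cdkn1a by 0.90 ± 0.13, Fkbp5 by 0.72 ± 0.12 (adjusted p = 0.000398, 5 of 5), Hif3a by 1.22 and Sult1a1 by 0.80. Sgk1 did not pass (0.16, adjusted p = 0.655; -0.03 without Abx morphine replicate 2). Microglia genes fell, 10 of 20 (16 adjusted over the list alone) and 0 rose, with median -0.34, adjusted p = 1.33e-15 and adjusted p = 0.123 with an estimated correlation: the fractalkine receptor gene Cx3cr1 (-0.44), the integrin gene Itgam (-0.46), Fcrls (-0.85) and Olfml3 (-0.91) were among them.

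Interferon-response genes were lower with morphine in Abx mice, 3 of 26 (5 adjusted over the list alone), with median -0.28, adjusted p = 0.0239 and adjusted p = 0.961 with an estimated correlation, Gbp3 (-0.80) among them. In the heat-shock list 3 of 16 fell (3 adjusted over the list alone), Chordc1 (-0.59) and Hsph1 (-0.42) among them, with median -0.13, adjusted p = 0.00639 and adjusted p = 0.961 with an estimated correlation. In the clock list 2 of 19 rose (2 adjusted over the list alone), Ciart (0.45) and Cry1 (0.41), with median 0.15, adjusted p = 0.00142 and adjusted p = 0.567 with an estimated correlation. The largest rises were those of Wnt10b, a signalling ligand gene, from 1.12 ± 0.235 to 5.65 ± 1.20 CPM (2.32 ± 0.24, adjusted p = 7.97e-07, 5 of 5 libraries), and of Itgad (2.08), Gabrr2 (1.36), Ccl17 (1.36), Tmprss6 (1.16), Acr (0.98), Oacyl (0.97), Maff (0.93) and Serinc4 (0.93). The fatty-acid binding protein gene Fabp7 fell most (-1.02 ± 0.12, adjusted p = 5.18e-06, 5 of 5 libraries), and among the other large falls were those of Hist1h2be (-0.99), Tcte2 (-0.95), Alas2 (-0.95), Tuba1c (-0.88), Lag3 (-0.88), Serpinh1 (-0.86), Dleu2 (-0.85) and Cd248 (-0.83). Oxidative phosphorylation (median -0.096) and ribosomal protein genes (-0.095) also passed as lower at the preset correlation, and Y-linked genes (0.25) as higher. Log2 fold changes of this comparison correlated across genes with gene length (rho 0.267) and GC content (rho -0.246). The edgeR test called 784 genes, 309 higher and 475 lower, and 9 lists passed camera, 0 with an estimated correlation. The count was 361 without Abx saline replicate 1, 265, 286 and 492 without Abx morphine replicates 1, 3 and 4, and 2462 by limma voom.

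**Figure D4:**
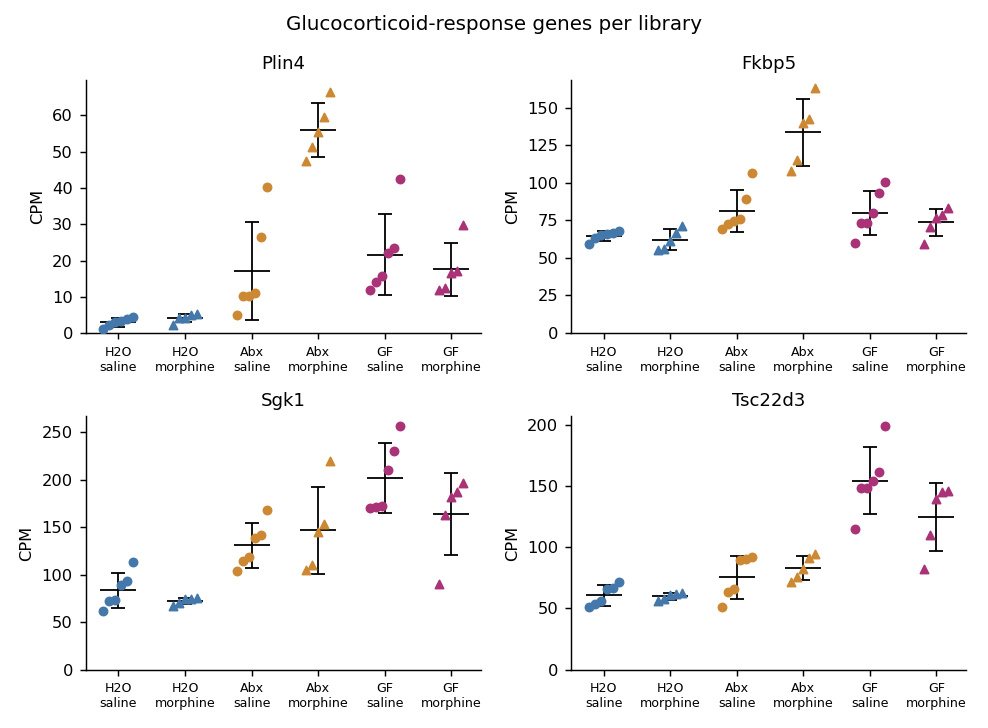
Plin4, Fkbp5, Sgk1 and Tsc22d3 in CPM per library in the 6 groups, with the mean and SD as bars. Plin4 averaged 56.1 ± 7.44 CPM in Abx morphine and 2.97 ± 1.20 CPM in H2O saline libraries.

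Morphine was compared with saline in GF mice to give the response without a microbiome. Flt3l, the gene of a blood-cell growth factor, rose from 2.98 ± 0.603 to 5.55 ± 0.893 CPM (0.92 ± 0.15, adjusted p = 0.0156, above every saline library in 5 of 5). No other gene passed the edgeR test, and 969 had an unadjusted p under 0.05. Next by p were Ednra (-0.71), Gpt2 (-0.28), Mfsd10 (0.48), Dph7 (0.28) and Spire1 (-0.40), all at an adjusted p of 0.408. Glucocorticoid-response genes were lower as a list, with 1 of 23 past the test adjusted over the list alone and 0 over all genes, median -0.13, adjusted p = 0.0173 and adjusted p = 0.774 with an estimated correlation. Ribosomal protein genes were higher, with 0 members past either test, median 0.10, adjusted p = 3.69e-20 and adjusted p = 0.774 with an estimated correlation. Log2 fold changes correlated here with GC content (rho 0.216) and gene length (rho -0.339). After their correction the median was 0.05. The meningeal list had 2 higher members adjusted over the list alone and 0 over all genes, with median 0.39, adjusted p = 0.00522 and adjusted p = 0.774 with an estimated correlation. The glutamatergic neuron list, a marker of dissection, had the largest absolute median of those past camera and passed as lower with 0 members past either test, median -0.47, adjusted p = 0.0115 and adjusted p = 0.774 with an estimated correlation. Interferon-response genes passed as higher, again with 0 members, median 0.26, adjusted p = 0.000827 and adjusted p = 0.774 with an estimated correlation, and a median of 0.01 without GF saline replicate 1 and GF morphine replicate 5. In GF morphine replicate 3 the connective-tissue and muscle genes Col3a1, Prg4, Atp2a1 and Mb stood at 79.3, 29.2, 6.52 and 7.38 CPM. Of 39 lists 9 passed camera, and 0 with an estimated correlation. The gene count was 0 without GF saline replicate 1, 2 or 3, without GF morphine replicate 1 or 6, by limma voom and in 7 other alternatives, and 2 without GF morphine replicate 3.

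GF morphine mice were compared with H2O morphine mice. Chaperone and glucocorticoid-response genes were higher and cholesterol genes lower in GF mice. In the heat-shock list 10 of 16 rose and 0 fell (15 and 0 adjusted over the list alone), with median 0.40, adjusted p = 3.76e-17 and adjusted p = 0.012 with an estimated correlation; Hspa5 rose by 0.89 ± 0.11 (adjusted p = 1.06e-05, 5 of 5 libraries) and Hspa8 by 0.50 ± 0.07. Of 23 glucocorticoid-response genes 12 rose and 0 fell (15 and 1 adjusted over the list alone), with median 0.29, adjusted p = 2.17e-12 and adjusted p = 0.012 with an estimated correlation; Plin4 rose by 2.04 ± 0.42, Zbtb16 by 1.39 ± 0.32, Sgk1 by 1.18 ± 0.19 and Tsc22d3 by 1.06 ± 0.15 (adjusted p = 0.000159, 5 of 5 libraries). Both lists lay above every H2O morphine library in 5 of 5 GF libraries. In the cholesterol list 8 of 23 fell and 0 rose (15 and 0 adjusted over the list alone), Dhcr7 (-0.44) among them, with median -0.33, adjusted p = 5.63e-11 and adjusted p = 0.153 with an estimated correlation. Ribosomal protein genes were higher, 13 of 77 (31 adjusted over the list alone), such as Rpl14 (0.36), with median 0.14, adjusted p = 6.91e-15 and adjusted p = 0.773 with an estimated correlation. The medium spiny neuron list passed as lower with 0 of 20 members past either test, median -0.27, adjusted p = 0.0227 and adjusted p = 0.797 with an estimated correlation. Interferon-response genes passed as higher, 2 of 26 (10 adjusted over the list alone), with median 0.30, adjusted p = 0.00752 and adjusted p = 0.773 with an estimated correlation, although the median was 0.10 without GF saline replicate 1 and GF morphine replicate 5. Microglia genes did so too, 1 of 20 (3 adjusted over the list alone), with median 0.12, adjusted p = 0.0417 and adjusted p = 0.773 with an estimated correlation.

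Among the largest rises in GF morphine mice were Rpph1 (3.25), Rmrp (2.86) and Rn45s (1.75), non-coding RNA genes that stood at 34.2, 27.3 and 19090 CPM in replicate 5. The muscle and connective-tissue genes Atp2a1 (3.70), Prg4 (3.15), Col3a1 (2.94), Mb (2.24) and Ogn (2.12) rose too, with Mb above the H2O range in 4 of 5 libraries and the others in 5 of 5; in replicate 3 Col3a1 stood at 79.3 and Prg4 at 29.2 CPM. Gh averaged 11.9 ± 13.4 CPM in GF morphine and 0.0900 ± 0.162 CPM in H2O morphine libraries. Apoo (2.14, 4 of 5 libraries) and Crh (1.75, 5 of 5) rose as well. Slc17a7 fell most (-5.93, 1 of 5 libraries below the H2O range), from 239 ± 423 CPM in H2O morphine, where 1 library stood at 990 and the others at 3.48 to 124, to 3.93 ± 0.583 in GF morphine libraries. It was followed by Gja5 (-1.57), Stra6 (-1.49), Dsg2 (-1.42), Sel1l3 (-1.32), Trib3 (-1.31), Cd163 (-1.30), Dsg1c (-1.30), Xrra1 (-1.26), Gkn3 (-1.18), Hs6st3 (-1.14) and Cstad (-1.12). The edgeR test called 844 genes, 482 higher and 362 lower, and 7 lists passed camera, 2 with an estimated correlation. It called 307 and 413 without H2O morphine replicates 3 and 5, 367 and 427 without GF morphine replicates 3 and 5, and 329 in a fit of both groups alone.

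Abx morphine mice were compared with H2O morphine mice. Glucocorticoid-response genes were higher in Abx mice: 14 of 23 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.53, adjusted p = 2.22e-23, and adjusted p = 0.000367 with an estimated correlation. The mean log2 CPM of the list was 5.60 ± 0.13 in Abx morphine, 4.75 ± 0.05 in H2O morphine, 5.15 ± 0.19 in Abx saline and 4.75 ± 0.06 in H2O saline libraries (SD). Plin4 stood at 56.1 ± 7.44 against 4.14 ± 1.10 CPM (3.73 ± 0.41, adjusted p = 3.02e-07, 5 of 5 libraries). Fkbp5 rose by 1.11 ± 0.12 (adjusted p = 3.4e-07, 5 of 5), Sgk1 by 1.02 ± 0.19 (adjusted p = 0.000467, 5 of 5), Hif3a by 2.05, Zbtb16 by 1.61, Sult1a1 by 1.54, Arrdc2 by 1.47, Pla2g3 by 1.42 and Cdkn1a by 1.34, and Wscd1 fell (-0.44). Microglia genes were lower, 15 of 20 (16 adjusted over the list alone) with 0 higher, median -0.40, adjusted p = 4.48e-18 and adjusted p = 0.0735 with an estimated correlation. The median was -0.30 with dissection covariates, and the list lay below every H2O morphine library in 5 of 5 Abx libraries; Olfml3 (-1.46), Fcrls (-1.19), the purinergic receptor gene P2ry13 (-0.83) and Itgam (-0.68) fell, while the growth-factor receptor gene Csf1r had -0.20 (adjusted p = 0.082).

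**Figure D5:**
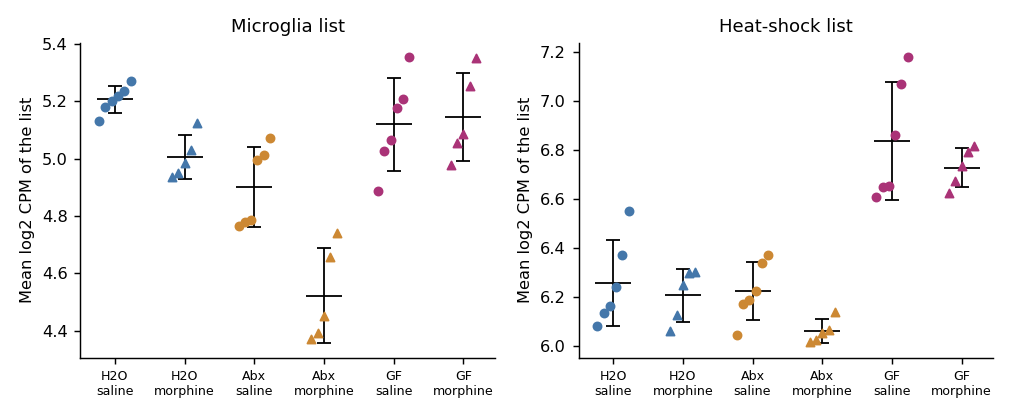
Mean log2 CPM of the microglia list (left) and the heat-shock list (right) per library in the 6 groups, with the mean and SD as bars. The microglia list averaged 4.52 ± 0.17 in Abx morphine and 5.01 ± 0.08 in H2O morphine libraries; the heat-shock list averaged 6.84 ± 0.24 in GF saline and 6.26 ± 0.18 in H2O saline libraries.

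Both oligodendrocyte lists passed as lower in Abx than in H2O morphine mice at the preset correlation alone. In the precursor list 3 of 14 fell and 0 rose (5 and 1 adjusted over the list alone), with median -0.32, adjusted p = 0.00457 and adjusted p = 0.683 with an estimated correlation, Olig2 (-0.68) and Gpr17 (-0.46) among them. In the myelin list 4 of 20 fell and 1 rose (4 and 1 adjusted over the list alone), with median -0.21, adjusted p = 0.0135 and adjusted p = 0.898 with an estimated correlation: Ugt8a (-0.91) fell, and the apolipoprotein gene Apod (0.68) rose. Interferon-response genes were lower, 4 of 26 (4 adjusted over the list alone), Isg15 (-1.17) and Gbp3 (-0.98) among them, with median -0.28, adjusted p = 0.0454 and adjusted p = 0.898 with an estimated correlation. Chaperone genes Chordc1 (-0.74) and Hsph1 (-0.54) fell with others, 4 of 16 (5 adjusted over the list alone), with median -0.14, adjusted p = 0.00457 and adjusted p = 0.811 with an estimated correlation. Clock genes were higher, 5 of 19 (5 adjusted over the list alone), Per1 (0.50), Ciart (0.45) and Cry2 (0.35) among them, with median 0.16, adjusted p = 0.000475 and adjusted p = 0.638 with an estimated correlation.

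Itgad (3.74), Ccl17 (2.27), Wnt10b (2.24), Gabrr2 (2.21), Tmprss6 (1.96) and Tnnt1 (1.79) were the other genes with the largest rises in Abx against H2O morphine mice. Rbm3 rose by 0.84 ± 0.09 and Cirbp, the gene of another cold-inducible RNA-binding protein, by 0.70 ± 0.12. The lipid transporter gene Mfsd2a (0.79) and Slc2a1 (0.31) rose, while the endothelial list they belong to did not pass (median -0.09, adjusted p = 0.589), with 3 of 20 higher and 4 lower. Fabp7 fell by 1.41 ± 0.12 (adjusted p = 5.93e-09, 5 of 5 libraries), and Oxt (-4.75, 3 of 5 libraries below the H2O range), Hist1h2be (-1.56), Cd180 (-1.39), Gpx6 (-1.31), Ninj2 (-1.30), Glt8d2 (-1.26), Ankk1 (-1.25) and Cass4 (-1.21) fell. Of 14602 genes 1518 passed the edgeR test, 663 higher and 855 lower, 93 of them over 2-fold, and 9 lists passed camera, 1 with an estimated correlation. The test called 2396 genes in a fit of both groups alone, 942 after thinning to 1 depth and 3548 by limma voom.

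The difference between the morphine responses of GF and H2O mice was tested as an interaction. No gene passed the edgeR test (0 of 14602, smallest adjusted p = 0.0665), with 2327 at an unadjusted p under 0.05, 234 called by DESeq2 and 42 by limma voom. The smallest p belonged to Lnpep (-1.22), Smg9 (0.45), Hspa1l (0.66), Nabp2 (0.37) and Cers6 (-0.82), and the interaction of Oprm1 was -1.12 (adjusted p = 0.148). Ribosomal protein genes had a higher response in GF mice (57 of 77 adjusted over the list alone, 0 over all genes), with median 0.23, adjusted p = 2.92e-32 and adjusted p = 0.461 with an estimated correlation, and so had oxidative phosphorylation genes (31 of 59, 0 over all genes), with median 0.23, adjusted p = 3.83e-22 and adjusted p = 0.461 with an estimated correlation. The interaction correlated across genes with gene length (rho -0.497) and GC content (rho 0.336). After their correction these medians were 0.13 and 0.09. They were 0.18 and 0.16 without GF saline replicate 1 and GF morphine replicate 5. The mean log2 CPM of oxidative phosphorylation genes was 7.27 in GF morphine replicate 5 and 6.90 to 6.95 in the other GF morphine libraries. The endothelial list had 5 higher and 1 lower members adjusted over the list alone, with median 0.20, adjusted p = 5.42e-05 and adjusted p = 0.497 with an estimated correlation, Cldn5 (0.73) and Ly6a (0.67) among the higher. In all 6 lists passed camera, 0 with an estimated correlation. Other splits of these libraries, which also exchange the states, passed a median of 9 lists at the preset correlation. The gene count was 61, 44 and 94 without GF saline replicates 1, 2 and 5, and 90, 22 and 5 without GF morphine replicates 2, 3 and 5.

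The difference between the morphine responses of Abx and H2O mice was tested in the same way. Wnt10b (2.46 ± 0.37, adjusted p = 0.000721), Pcolce2 (1.27), Cdkn1a (1.25 ± 0.19, adjusted p = 0.000721), Fkbp5 (0.78 ± 0.17, adjusted p = 0.047), Mfsd2a (0.67) and Dbndd2 (0.40) had higher responses in Abx mice. Fabp7 (-1.16 ± 0.16, adjusted p = 0.000466), Arhgef19 (-0.73), Stxbp4 (-0.73), Mettl16 (-0.70), Fer1l5 (-0.61) and Pycrl (-0.59) had lower ones. In morphine against saline, Wnt10b, Cdkn1a, Fkbp5 and Fabp7 each lay beyond the saline range in 5 of 5 Abx libraries. Glucocorticoid-response genes had a higher response in Abx mice, 2 of 23 (5 adjusted over the list alone), with a median of 0.25, adjusted p = 8.99e-12, and adjusted p = 0.0223 with an estimated correlation; Map3k6 had 0.95 (adjusted p = 0.102). Microglia genes had a lower response as a list (2 of 20 adjusted over the list alone, 0 over all genes), with median -0.17, adjusted p = 0.00422 and adjusted p = 0.867 with an estimated correlation. The glutamatergic neuron list passed as higher although its median was 0.02 and its mean -0.03, with adjusted p = 0.0406, and adjusted p = 0.867 with an estimated correlation. The edgeR test called 16 genes, 7 higher and 9 lower, with 1157 at an unadjusted p under 0.05, and 7 lists passed camera, 1 with an estimated correlation. The gene count was 6 without H2O saline replicate 3, 9 without Abx saline replicate 1, 3, 9 and 9 without H2O morphine replicates 2, 3 and 6, 6, 25 and 6 without Abx morphine replicates 1, 2 and 3, and 67 by DESeq2.

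Morphine responses of the microbiome states were set against each other across the 14602 genes, which are not independent replicates. Pearson r of the log2 fold changes was 0.248 between H2O and Abx mice, -0.101 between H2O and GF mice and -0.118 between Abx and GF mice. The second of these was 0.134 without H2O morphine replicate 4. Between the GF and Abx differences from H2O in saline mice r was 0.361, both sharing the H2O libraries. With the 6 H2O saline libraries split 3 and 3 over 20 splits, r averaged 0.205. In simulated groups that differed from the shared controls by chance alone it averaged 0.474. Both higher were 5 genes, where 1.62 were expected from the separate counts, and both lower 4, where 1.20 were expected. These expected numbers take both comparisons as independent, and shared H2O libraries alone can raise the overlap above them. The number of lists past camera at the preset correlation was reached by 8 to 90 of 100 splits of the libraries, depending on the comparison.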

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

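The tests of depth by thinning, of GC content and length on the genes that kept their call, of dissection covariates and colony on the breadth of the GF difference, and of the spread among microglia genes were chosen only after the results were seen. For the other tests of this part the prediction was written before the value it concerns was seen, although the correction of GC content and length that some of them use was itself added after seeing the data.

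The difference between GF and H2O saline mice covered 4807 genes. A difference in depth was argued against as its whole cause, since 3957 genes passed after all libraries were thinned to 1 depth. The highest of the other splits thinned alike gave 2423. A different share of glutamatergic neurons was argued against as the whole cause too. With glutamatergic neuron and myelin levels as covariates 4922 genes passed, and 2388 in the highest of the other splits with them. The myelin level (mean log2 CPM ± SD) was 6.89 ± 0.49 in GF and 6.95 ± 0.08 in H2O saline libraries, so this covariate could remove little. Hypothalamic (1.70 ± 1.28 against 0.61 ± 0.38) and choroid plexus markers (3.24 ± 0.44 against 2.65 ± 0.21) were not covariates. A shift of the dissection toward those tissues was therefore not tested. GC content and length were argued against as the whole cause for 1807 of 4776 called genes with known length, which kept call and direction after the correction, against 1080 in the highest of the other splits corrected alike. The 1080 are all calls of that split, and all calls of the real grouping after the correction were 2521. Other splits speak only to chance, in this test and those above, because a cause that follows the real grouping would also set it above them. The median log2 fold change of the 1807 genes in the first direction also shrank, from 0.46 to 0.36. For the other 2969 genes the median log2 fold change in the first direction went from 0.31 to 0.12 while the median standard error went from 0.0883 to 0.0770, so they lost their call because the change shrank, and bias and biology cannot be told apart there. Colony or facility and germ-free status cannot be told apart either, because every GF mouse came from a facility of its own, conventional mice were those of an earlier publication, and 5 of the 7 tested genes known to differ between C57BL/6 substrains passed, although all mice are labelled C57BL/6J: Ide (-0.72), Fgfbp3 (-0.85) and Entpd4 (-0.80) lower, Gabra2 (0.57) and Wdfy1 (0.33) higher. Over all tested genes 32.9% passed in this comparison, and the substrain gene Nnt did not pass.

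Glucocorticoid-response genes were higher in Abx morphine than in H2O morphine mice, with a median log2 fold change of 0.53. The dissected share of glutamatergic neurons or myelin was argued against as the cause by a median of 0.50 with their levels as covariates, and GC content and length by a median of 0.53 after their correction. A different time of day at dissection predicted clock genes of opposite phase changing in opposite directions, and 0 of 6 did so. That prediction was too narrow, because 5 other clock genes passed, so time or order of dissection cannot be told apart from the groups, and the labels give neither, nor the cage of each mouse. A candidate explanation is a higher glucocorticoid tone in mice given both antibiotics and morphine; hormone levels were not measured.

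Microglia genes were lower in Abx morphine than in H2O morphine mice, with a median of -0.40, although the list did not pass with an estimated correlation (adjusted p = 0.0735). GC content and length were argued against by a median of -0.39 after their correction. Fewer microglia with unchanged cells would lower all markers by about 1 amount, and it was argued against by 8 of 20 members whose 95% intervals leave out the median. A different share of glutamatergic neurons or myelin stays open in part, since the median was -0.30 with covariates, and it cannot be told apart for that part of the change. A change within microglia may remain as a hypothesis, alone or with a change in their number.

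Chance as the reason for a gene count was tested with 100 splits of the compared libraries, the real one included. The splits treat each mouse as an independent unit. Whole cages were assigned to a drink, and the cage of each mouse is not given. Chance differences between cages can therefore stay with the real grouping and were not tested. Chance among single mice was excluded for GF against H2O saline mice (1 split gave as many, real 4807, highest other 3020), Abx against H2O saline (1 split, 17 and 1), GF against Abx saline (1 split, 3990 and 3290), morphine in Abx mice (1 split, 784 and 74), GF against H2O morphine (1 split, 844 and 138) and Abx against H2O morphine (1 split, 1518 and 277). For the interaction of Abx mice 2 splits gave as many as the real 16, and the highest other gave 396. Differences between states can enter those splits, so the test cannot decide there. Chance was not excluded for morphine in GF mice (25 splits, 1 and 2462). Morphine in H2O mice and the interaction of GF mice had 0 genes, which any split reaches, so the test says nothing there (highest other 2 and 1980). The split with 2462 genes moved 6 libraries and is far above the real count of 1, which points to structure among the GF libraries that their groups do not describe. The splits with 3020 and 3290 genes moved 10 and 2 of 12 libraries, so they mostly repeat the real difference, the first of them reversed. Splits that moved 6 of 12 libraries gave up to 372 and 250 genes in these comparisons, so some structure of that kind is present there too. In the interactions the states were exchanged within saline and within morphine mice, so a difference between states can enter the splits with 1980 and 396 genes.

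For the number of lists past camera at the preset correlation, chance was not excluded in any of the 10 comparisons. The median of the other splits ran from 6 lists for morphine in H2O mice to 11 in GF against Abx saline mice. A list that passed at the preset correlation alone is therefore weak evidence, however small its p-value. In GF against H2O saline mice 47 splits of 100 gave as many as the real 11, the highest other 19. In Abx against H2O saline it was 8 splits (real 13, highest 15), in GF against Abx saline 87 (8 and 20), in morphine in H2O mice 24 (8 and 12), in Abx mice 39 (9 and 16) and in GF mice 63 (9 and 21). In GF against H2O morphine it was 90 (7 and 17), in Abx against H2O morphine 32 (9 and 14), in the interaction of GF mice 88 (6 and 18) and in that of Abx mice 73 (7 and 15).

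Chance was not excluded for r between morphine responses either. With saline and morphine regrouped within the second state and r taken from differences of means, 24 of 100 regroupings gave an absolute r as large as the 0.266 of H2O and Abx mice (highest other 0.441), 86 as large as the -0.0349 of H2O and GF mice (0.419) and 14 as large as the -0.154 of Abx and GF mice (0.244). For the GF and Abx differences in saline mice, chance differences among single shared H2O libraries were argued against as the whole cause of the covariance. It was 0.0261 with all controls and 0.0161 on average with the H2O libraries in separate sets. A deviation common to all H2O saline mice would stay in both sets and was not tested.

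Single libraries stood far from the others of their group in 10 of 120 sets of values tested, where chance gives about 1 in 20, or 6. GF saline replicate 1 had 15.3 M gene reads, the others 4.87 to 8.13. Its Hspa5 and Tsc22d3 levels lay beyond those of all conventional libraries, as in most GF libraries. Both genes were called higher in GF saline mice with this library included, and its label could not be checked. H2O saline replicate 5 had 11.9% of reads aligned to several places, the others 10.4% to 10.8%, and GF morphine replicate 6 had 1.32% ambiguous reads, the others 1.24% to 1.26%. Drd1a stood at 139 CPM in Abx saline replicate 5 and at 239 to 280 in the others. H2O morphine replicate 4 had 4.45 CPM of Oprm1 (others 7.99 to 8.86), 841 of Penk (1266 to 1371) and 229 of Pdyn (392 to 448). Pdyn stood at 492 CPM in GF morphine replicate 1 and at 275 to 319 in the others. The mean log2 CPM of the glucocorticoid list was 5.68 in GF saline replicate 5 (others 5.28 to 5.42), and that of oxidative phosphorylation was 7.27 in GF morphine replicate 5 (6.90 to 6.95).

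Morphine responses differed between Abx and H2O mice for 16 genes in the test of the interaction. Higher in Abx mice were Wnt10b (2.46), Pcolce2 (1.27), Cdkn1a (1.25), Fkbp5 (0.78), AI854517 (0.68), Mfsd2a (0.67) and Dbndd2 (0.40). Lower were Tufm (-0.40), Tmco3 (-0.42), Lasp1 (-0.43), Pycrl (-0.59), Fer1l5 (-0.61), Mettl16 (-0.70), Stxbp4 (-0.73), Arhgef19 (-0.73) and Fabp7 (-1.16). The response of Wnt10b was 2.32 in Abx and -0.14 in H2O mice, that of Cdkn1a 0.90 and -0.35, that of Fkbp5 0.72 and -0.06, and that of Fabp7 -1.02 and 0.14. Without single libraries the number of genes ran from 3 to 25: it was 6 without H2O saline replicate 3, 9 without Abx saline replicate 1, 3, 9 and 9 without H2O morphine replicates 2, 3 and 6, and 6, 25 and 6 without Abx morphine replicates 1, 2 and 3.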

How the results depend on the processing

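The genes of the normalised table, GC and length correction, thinning, and leaving out GF saline replicate 1 with GF morphine replicate 5 (both libraries in doubt, the first with some values like those of conventional mice) were chosen after seeing the data. Counts of genes or lists within 1.5 times the reported one are mostly not given; the cause of the other values was not tested unless stated. RLE factors, upper-quartile factors, no filter and the CPM filter left every count of genes within that range. Named genes past the threshold were followed under all alternatives set beforehand, apart from leaving out single libraries. In GF against H2O saline mice 60 of 71 passed with the same sign under all of these. It was 4 of 16 in Abx against H2O saline and 17 of 35 in GF against Abx saline. For morphine it was 28 of 35 in Abx mice and 0 of 1 in GF mice. It was 11 of 32 in GF against H2O morphine, 42 of 46 in Abx against H2O morphine and 5 of 16 in the interaction of Abx mice. With alternatives added after seeing the data too, these were in order 51 of 71, 3 of 16, 16 of 35 and 24 of 35. For the other comparisons, in the same order, they were 0 of 1, 11 of 32, 39 of 46 and 4 of 16. With each library left out in turn, 62 of 71, 4 of 16, 20 of 35, 24 of 35, 0 of 1, 20 of 32, 42 of 46 and 3 of 16 always passed, in the same order.

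For Abx against H2O saline mice 17 genes became 32 with GC and length correction, 100 by DESeq2, 187 by limma voom, 53 in a fit of the groups compared, 4 with a replicate block, 62 with dissection covariates, 6 after thinning and 36 at a threshold of 0.10. For GF against H2O saline 4807 became 2521 with GC and length correction, and for GF against Abx saline 3990 became 2164 with it and 2278 in a fit of the groups compared. The 0 genes of morphine in H2O mice became 332 by DESeq2, 1314 by limma voom, 989 in a fit of the groups compared, 3 with dissection covariates, 2 after thinning, 190 at 0.10, 176 with a surrogate variable and 6 over the genes of the normalised table. The 784 of Abx mice became 2462 by limma voom, 1300 with dissection covariates, 364 after thinning and 1361 at 0.10. The 1 of GF mice became 0 by limma voom, in a fit of the groups compared, with a replicate block, with dissection covariates, after thinning, with a surrogate variable, over the genes of the normalised table and without both libraries in doubt.

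For GF against H2O morphine 844 became 329 in a fit of the groups compared, 514 after thinning, 1632 at 0.10 and 341 with a surrogate variable. For Abx against H2O morphine 1518 became 3548 by limma voom, 2396 in a fit of the groups compared, 942 after thinning and 2334 at 0.10. The 0 of the GF interaction became 234 by DESeq2, 42 by limma voom, 25 with dissection covariates, 80 at 0.10, 22 with a surrogate variable, 30 over the genes of the normalised table and 7 without both libraries in doubt. The 16 of the Abx interaction became 25 with GC and length correction, 67 by DESeq2, 172 by limma voom, 59 in a fit of the groups compared, 9 with a replicate block, 47 with dissection covariates and 5 after thinning. A threshold of 0.10 is looser by construction and thinning leaves fewer reads. Replicate numbers did not pair mice, so the block has no known meaning.

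With an estimated correlation the lists past camera became 0 of 11 in GF against H2O saline, 2 of 13 in Abx against H2O saline, 1 of 8 in GF against Abx saline, 0 of 8, 0 of 9 and 0 of 9 for morphine in H2O, Abx and GF mice, 2 of 7 in GF and 1 of 9 in Abx against H2O morphine, 0 of 6 in the GF and 1 of 7 in the Abx interaction. With GC and length correction they were 13 for morphine in H2O mice and 11 in the GF interaction. They were 11 in the Abx interaction in a fit of the groups compared, and 4 in GF against H2O morphine without both libraries in doubt. Without those libraries 6043 genes passed in GF against H2O saline, 5276 in GF against Abx saline and 630 in GF against H2O morphine.

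Leaving out each library in turn gave 3598 to 5603 genes in GF against H2O saline, 4 to 31 in Abx against H2O saline, 2893 to 4861 in GF against Abx saline, 0 to 2, 265 to 840 and 0 to 2 for morphine in H2O, Abx and GF mice, 307 to 1227 in GF and 1025 to 1571 in Abx against H2O morphine, 0 to 94 in the GF and 3 to 25 in the Abx interaction. The correlation r of morphine responses ran from 0.178 to 0.306 for H2O and Abx, -0.188 to 0.134 for H2O and GF, with 0.134 without H2O morphine replicate 4, and -0.202 to -0.0559 for Abx and GF mice; r of the GF and Abx differences in saline mice ran from 0.295 to 0.427. Signs turned for Drd1a in GF against H2O saline (-0.292 to 0.0138 over the libraries left out, the highest without GF saline replicate 5), Nnt there (-0.0715 after thinning), Gal in GF against Abx saline (-0.42 with dissection covariates) and Sgk1 for morphine in Abx mice (-0.0259 to 0.274, the lowest without Abx morphine replicate 2), none of them called except Gal. The direction that camera gave turned for ribosomal protein genes in GF against H2O saline, whose median was -0.10 and then 0.00699 with GC and length correction, and for interferon-response genes for morphine in GF mice, whose median of 0.26 shrank to 0.0104 without both libraries in doubt and kept its sign. At the depth used, changes of 1.5-fold were recovered in 40.3% to 73.1% of simulated genes, so smaller ones were often not detectable.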

Other observations

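The count of genes past the threshold in both saline and morphine mice was chosen after the results were seen; the lists of this part were fixed beforehand. Immediate-early genes, which neurons switch on with activity, included 7 of 24 that rose and 1 that fell in GF against H2O saline mice (7 and 1 adjusted over the list alone), although the list as a whole did not pass (adjusted p = 0.101). The list passed as higher in Abx against H2O saline mice (median 0.20, adjusted p = 0.00914 and adjusted p = 0.751 with an estimated correlation), for morphine in Abx mice (median 0.27, adjusted p = 0.0342 and adjusted p = 0.961 with an estimated correlation) and in Abx against H2O morphine mice (median 0.23, adjusted p = 0.0135 and adjusted p = 0.898 with an estimated correlation). Of its members 0, 0 and 1 passed the threshold. In GF against H2O saline mice Nr4a3 (1.88), Egr2 (1.42), Nr4a1 (1.29) and Fosb (1.06) rose and Ier5 (-0.61) fell. Of 12 serotonin receptor genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), Htr1b (0.98) and Htr7 (0.75) upward and Htr6 (-0.74) downward. Of 23 genes of histone acetylation enzymes 5 rose and 1 fell (5 and 1 adjusted over the list alone), the deacetylase genes Hdac4 (0.81) and Sirt1 (0.71) upward and the acetyltransferase gene Kat2a (-0.20) downward. In the clock list 4 of 19 rose and 2 fell (4 and 2 adjusted over the list alone), Clock (0.51) and Dbp (-0.61) among them. None of these lists passed camera in GF against H2O saline mice.

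Ribosomal protein genes were lower in GF than in H2O saline mice as a list, with 13 of 77 lower and 2 higher (7 and 0 adjusted over the list alone), median -0.10, adjusted p = 0.00104 and adjusted p = 0.927 with an estimated correlation, and a median of 0.01 with GC and length correction. Of 4 Y-linked genes tested 2 rose and 0 fell (2 adjusted over the list alone), Uty (0.89) and Ddx3y (0.42), with median 0.36, adjusted p = 0.0461 and adjusted p = 0.553 with an estimated correlation. Among markers of neighbouring hypothalamic tissue 4 of 6 rose and 0 fell (4 adjusted over the list alone), and the list did not pass (adjusted p = 0.0558). The nicotinamide nucleotide transhydrogenase gene Nnt, in which a common substrain carries a deletion, had a log2 fold change of 0.06 (adjusted p = 0.471; -0.07 after thinning) in GF against H2O saline and fell by 0.44 in Abx against H2O morphine mice. Ide, another substrain gene, fell in GF against Abx saline (-0.82) and in GF against H2O morphine mice (-0.87). Gabra2 fell in Abx against H2O morphine mice (-0.73). With morphine in Abx mice, Rbm3 (0.38), Cirbp (0.45) and Mfsd2a (0.46) rose, and Oprm1 had 0.38 (adjusted p = 0.442).

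The saline and morphine comparisons of a state with H2O mice share no library. Of 844 genes past the threshold in GF against H2O morphine mice, 597 also passed with the same sign in saline mice, 351 higher and 246 lower, where 86.6 and 54.2 were expected from the separate counts, and 1 passed with the opposite sign. The 597 were 263 and 341 without GF morphine replicates 3 and 5, 232 and 315 without H2O morphine replicates 3 and 5. They were 232 in a fit of the groups compared, 251 with a surrogate variable, 358 after thinning, 924 by limma voom, 1103 at a threshold of 0.10 and 474 with GC and length correction. For Abx against H2O mice 13 genes passed in both, 5 higher and 8 lower, where 0.409 and 0.468 were expected, and 1382 of the 1518 genes past the threshold in morphine mice had the same sign in saline mice. Those 13 were 4 without H2O saline replicate 5 or 9 or Abx saline replicate 4, 5 and 7 without H2O saline replicates 8 and 6, 6 without Abx saline replicate 5 or 6, and 23 and 20 without Abx saline replicates 1 and 3. They were 71 by DESeq2, 144 by limma voom, 39 in a fit of the groups compared, 52 with dissection covariates, 27 with GC and length correction, 28 at a threshold of 0.10, 4 with a replicate block and 5 after thinning. The GF mice of both comparisons came from 1 facility, and any batch shared by GF or by conventional mice is shared by both comparisons.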
